A study of Mus musculus with 2 samples.

How the data were processed

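The data are droplet single-cell RNA counts from 1 male and 1 female library of cells sorted from tumours, which the labels describe as viable CD4+ T cells. The deposited count matrices hold whole-number UMI counts per gene and barcode, which the authors made with Cell Ranger 7.0.1, per the file headers. The genome build GRCm38 and Seurat 5 are named in the submitters' processing notes, with no role stated. The annotation release and the settings of the cell caller are not stated in the sources used here. Every barcode in the files has at least 500 UMIs. The number of mice behind each library is not stated. Each matrix has 32285 genes, of which 99.6% matched a GENCODE M21 gene by Ensembl identifier, and coordinates were taken from that annotation on GRCm38.

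Everything else was computed from the counts with Python 3.11.15, scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9 and matplotlib 3.10.9. Barcodes with at least 500 genes and at most 10% mitochondrial UMIs were kept, 3468 of 3658 in the female and 3519 of 3708 in the male library. Scrublet (expected rate 0.03) called 0 of the 7366 barcodes as doublets. Clusters with markers of more than 1 cell type remained, so the 0 calls do not show that doublets are absent. Both libraries were clustered jointly: counts per 10000, log1p, 2000 variable genes chosen within library, 30 principal components, 15 neighbours and Leiden resolution 1, with a fixed seed and no integration. Xist, Tsix, Y genes, T cell receptor and immunoglobulin segments, mitochondrial and ribosomal protein genes and Cd40lg were left out of the clustering.

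Cluster names were rebuilt from marker genes, and their thresholds were set after the data were seen. A cluster was called low-UMI where its median was under the library median divided by 3, epithelial or tumour-like above 500 CPM Krt8, natural killer-like above 100 CPM Ncr1 (no cluster), and mixed where at least 25% of barcodes held at least 1 Foxp3 UMI and at least 2 Cd8a or Cd8b1 UMIs, or where Cd3e above 200 CPM met Lyz2 above 100 CPM or Col1a1 above 200 CPM. The rest were CD4 T-like where Cd4 exceeded Cd8a and Cd8b1 together (Treg-like above 100 CPM Foxp3), and otherwise Cd8-high.

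UMIs were summed per library and class, divided by the total and compared as log2 ratios with the exact 95% interval of a ratio of Poisson counts. A count of 0 was set to 3 counts. Ratios of thinned cells use 1 draw with a fixed seed. With 1 library per sex, no test, p-value or standard error was made from cells. A gene was measured with at least 10 CPM in 1 library and at least 20 UMIs over both. For each of 23 gene lists fixed before the data were examined, the median log2 ratio of its measured members was set beside 10000 random lists of the same size matched on expression in 20 bins, with an interval from 1000 Poisson draws. A list needed 3 measured members for this. Random genes were drawn independently of each other, while members of a fixed list can be expressed in the same cells and differ together. A place outside the random range therefore describes a list and is not a test of it. A further 13 lists of markers of other cell types were summed. Trbv segments were assigned by the most counted segment with at least 2 UMIs.

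Genes were named by a rule fixed before the data were examined: the sex genes and Cd40lg, up to 4 members per list with the largest ratios and at least 50 UMIs, the 12 highest and 12 lowest ratios in CD4 T-like cells that had the same sign in both classes, with no size asked of either class, and the 5 highest and 5 lowest in each class. The last groups needed at least 20 CPM in 1 library, a ratio of at least 1.5-fold and an interval bound of at least 1.25-fold. Predicted genes, sex genes, receptor segments, and mitochondrial and ribosomal protein genes were left out of them. For the Cd8-high clusters, a rule added later took genes with the same direction in the 5 largest clusters and at least 1.5-fold in 3 of them.

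The share of cells with a Cd40lg UMI was planned after thinning each cell to the 10th percentile of UMIs (2977), with shallower cells left out. The share given is the exact mean over all thinning draws. This replaced a single draw after 2 single draws were seen to differ by several percentage points, and the range over draws is given in the closing section.

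The steps were tested on simulated counts with 200 changed genes per comparison. In CD4 T-like, Treg-like and other CD4 T-like cells (7746, 7834 and 7547 genes), the naming rule recovered 97%, 91% and 66% of genes changed by a log2 of 1 and 100% of those changed by a log2 of 2. It named 2, 4 and 18 unchanged genes. Intervals held the true ratio for 95.0%, 95.9% and 96.2% of genes. The simulated counts were Poisson, as the intervals assume, with no spread between cells or mice. These figures therefore check the computation only and do not show how the steps perform on real counts.

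Alternatives fixed before the data were examined were edgeR 4.0.16 TMM factors and DESeq2 1.42.0 median-of-ratios factors (R 4.3.3), totals without mitochondrial, ribosomal protein and T cell receptor genes, equal weight per cell, thinned cells, other list minimums, doublets kept, other cell filters (at least 1000 genes and at most 5% mitochondrial, or all barcodes), Leiden resolutions 0.5 and 2, Foxp3 UMIs in place of clusters, all kept cells, no cycling clusters, and unthinned shares. Those added after the data were seen left out genes that hold ribosomal RNA reads, barcodes with 2 or more Trbv segments, cells with a Cd8a or Cd8b1 UMI, the Klrg1-led finer cluster, cells with Trbv12-2, or the top cell per gene, or added cluster 11 to the Treg-like class, or used 1 thinning draw.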

Results

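Gene expression was counted in single cells from MB49 tumours, a transplanted mouse bladder tumour line, taken on day 14 from male and female C57BL/6J mice aged 12 to 14 weeks. The labels describe a sort of viable CD4+ T cells, of which 10000 to 20000 were loaded per library on a droplet kit that reads the start of each transcript. There was 1 library per sex, so no value below has a replicate check and no difference was tested against the spread between mice. The female library held 3658 barcodes and 55880364 unique molecular identifiers (UMIs), with a median of 8915.5 per barcode. The male library held 3708 barcodes and 50946624 UMIs, with a median of 7494. After filtering, 3468 female and 3519 male cells remained. Intervals are 95% intervals and cover counting error only. They are exact for counts (Poisson), shares and ratios (Clopper-Pearson), are combined from exact bounds for differences of shares, and come from random draws of counts for medians of gene lists and values at equal class weights. Ratios are given as log2 of female over male CPM (UMIs of a gene scaled to the UMI total of the cells compared), so that positive values are higher in the female library.

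The sex labels were checked first. Xist, the RNA made from the inactive X, had 12520 UMIs in the female library and 0 in the male library, where 0 allows up to 0.0589 CPM at 3 counts. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 2274, 4415, 543 and 1690 UMIs in the male library. In the female library these genes had 0, 0, 0 and 1 UMIs.

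Most cells were not CD4 T cells by their transcripts, although the labels state a CD4 sort. Cd8a, a chain of the CD8 co-receptor, had 35935 UMIs in the female and 29719 in the male library, against 1859 and 2156 UMIs of Cd4. Joint clustering gave 17 clusters, which were named from marker genes by thresholds set after the data were seen. Clusters with more Cd8a and Cd8b1 than Cd4 (Cd8-high) held 57.2% of female cells (55.5% to 58.9%) and 53.4% of male cells (51.7% to 55.1%). CD4 T-like clusters held 15.6% (14.4% to 16.8%) and 17.1% (15.9% to 18.4%). A further 21.5% of female and 21.0% of male cells fell in 4 mixed clusters, which carried markers of more than 1 cell type and a median of 31028 and 31479.5 UMIs per barcode. A cluster of low UMI number held 4.50% and 7.62%, and a cluster led by the keratins Krt8 and Krt18 (epithelial or tumour-like) held 1.18% and 0.853%. Classes were set per cluster, so any CD4 T cells in other clusters are not counted as CD4 T-like. Cd4 stood at 281 and 173 CPM in the CD4 T-like clusters 1 and 5. It was at 62.0 CPM in mixed cluster 11, 54.8 CPM in Cd8-high cluster 12 and 1.97 CPM in Cd8-high cluster 7.

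**Figure D1:**
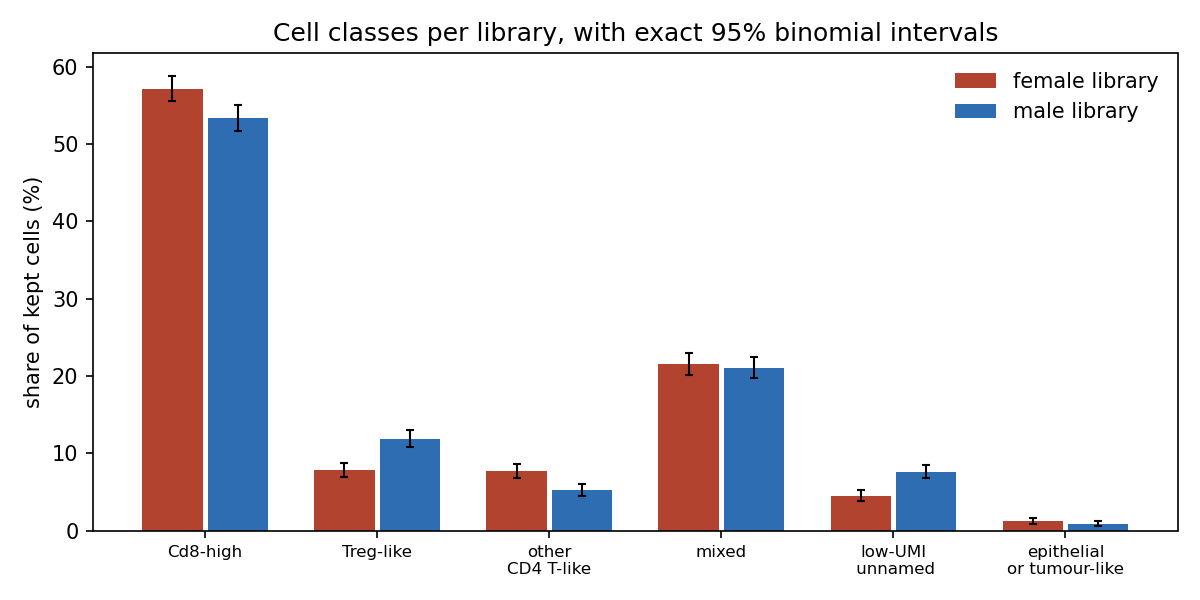
Share of kept cells (%) in each class for the female and male library. Bars start at 0 and error bars are exact 95% binomial intervals; Cd8-high cells made up over 50% of both libraries.

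Within the CD4 T-like cells, regulatory T cell-like (Treg-like) cells took a smaller share of the female library. Treg-like cells formed cluster 5, led by Foxp3, the lineage factor of regulatory T cells, with Ikzf2 and Tnfrsf4. They were 272 of 540 CD4 T-like cells in the female library (50.4%, 46.1% to 54.7%) and 419 of 602 in the male library (69.6%, 65.8% to 73.3%), a difference of -19.2 percentage points (-24.9 to -13.5). The other CD4 T-like cells, cluster 1 with Cd4, Tcf7 and Tnfsf8 among its leading genes, were 268 female and 183 male cells. A mixed cluster also led by Foxp3 (cluster 11, 251 female and 300 male barcodes) was kept out of the Treg-like class because 68.6% of its barcodes held a Foxp3 UMI together with at least 2 Cd8a or Cd8b1 UMIs. Sorting and tissue digestion can set such shares.

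The series title names CD4 help and the CD40L-CD40 pathway, so Cd40lg, which encodes CD40L, was compared next. Over all CD4 T-like cells Cd40lg stood at 71.6 CPM in the female and 42.4 CPM in the male library (246 and 158 UMIs), a log2 ratio of 0.76 (0.46 to 1.06). Within the classes the ratio was smaller or pointed the other way. Other CD4 T-like cells held most Cd40lg UMIs of the CD4 T-like cells, 233 female and 125 male. In them Cd40lg was at 159 against 141 CPM (log2 0.18, -0.14 to 0.50). In Treg-like cells it was 6.60 against 11.6 CPM (log2 -0.82, -1.87 to 0.15), from 13 and 33 UMIs. With both libraries set to the same class weights the log2 ratio of Cd40lg was 0.07 (-0.22 to 0.37). Over all kept cells of each library it was -0.04. Those cells include Cd8-high cells, with 224 female and 245 male Cd40lg UMIs, and mixed cells, with 149 and 175. Cd40lg (ENSMUSG00000031132) lies on chromosome X at 57212143 to 57224042 (GRCm38).

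The share of other CD4 T-like cells with a Cd40lg UMI was 42.9% (36.9% to 49.1%) in the female and 33.9% (27.1% to 41.2%) in the male library, at median depths of 4677 and 4248 UMIs. After each cell was thinned to 2977 UMIs, averaged over all possible draws, the shares were 31.6% (25.8% to 37.8%) of 244 cells and 26.7% (19.9% to 34.7%) of 149 cells. The difference of 4.90 percentage points (-5.05 to 14.0) was not detectable at this depth. Cells with a Cd40lg UMI held 2.03 and 2.02 Cd40lg UMIs on average before thinning. As a background, 0 of 41 female and 0 of 30 male tumour-like cells had a Cd40lg UMI, which allows up to 7.32% and 10% at 3 cells (exact upper bounds 8.60% and 11.6%). Those cells had medians of 53084 and 38848.5 UMIs. In Cd8-high cells the shares were 5.39% and 6.87%, at medians of 8845 and 7698 UMIs.

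**Figure D2:**
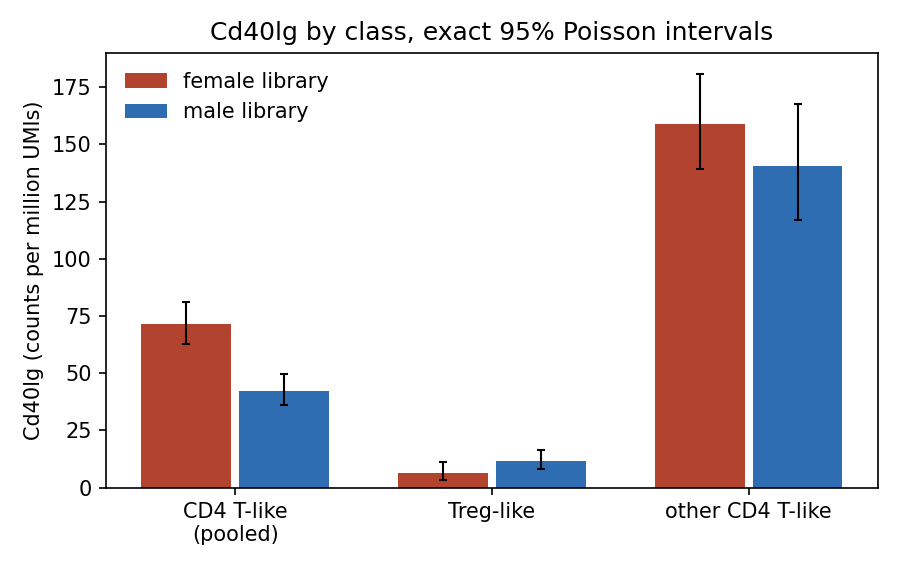
Cd40lg in CPM in the pooled CD4 T-like cells and in each class, per library, with bars from 0 and exact 95% Poisson intervals. The pooled values of 71.6 and 42.4 CPM lie further apart than the values within other CD4 T-like cells, 159 and 141 CPM.

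Other CD4 T-like cells of the female library carried more transcripts of T helper 1 (Th1), cytotoxic and interferon-response genes, and fewer of naive and Th17 genes. Values of these lists in the Cd8-high clusters are not given here, so the pattern is not shown to be particular to this class. Of 17 measured Th1 genes, 9 were at least 1.5-fold higher in the female library and 0 lower. The median log2 ratio was 0.77 (0.40 to 1.03), at or above all of 10000 random lists matched on expression (95% of them from -0.10 to 0.19). Ifng, the cytokine interferon gamma, had 292 female and 37 male UMIs (log2 2.26, 1.76 to 2.79). The receptor chains Il12rb2 (2.52, 1.98 to 3.12) and Il18rap (2.10, 1.60 to 2.63) and the chemokine receptor Cxcr6 (1.69, 1.35 to 2.03) were also higher. The cytotoxic list had a median of 0.77 (0.59 to 1.05), with 9 of 14 genes at least 1.5-fold higher and 0 lower. At Leiden resolution 2 the cytotoxic median was 0.20, inside the random range of -0.14 to 0.24. Its members included Nkg7, a protein of cytotoxic granules (1.20, 0.97 to 1.43), Ctsw (1.52, 1.05 to 2.02) and the receptor Klrc1 (1.04, 0.42 to 1.71; -0.60 at Leiden resolution 2). Ccl4 (2.82, 1.51 to 4.49) rested on 1 female cell with 70.7% of its UMIs and was -3.71 at Leiden resolution 2.

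Genes induced by type I interferon had a median of 0.78 (0.34 to 0.91) in these cells, with 7 of 12 at least 1.5-fold higher and 0 lower. Irf7, a factor that drives interferon transcription, had a log2 ratio of 1.64 (1.22 to 2.08) and the nucleic acid sensor Zbp1 1.02 (0.54 to 1.52). With a stricter cell filter the list median was 0.04, inside its random range of -0.18 to 0.26. The interferon gamma response list had a median of 0.48 (0.21 to 0.57), with 7 of 19 genes higher and 0 lower by 1.5-fold, among them the GTPases Igtp (0.97, 0.63 to 1.33) and Gbp6 (0.74, 0.31 to 1.18). That median was 0.18 with the stricter filter and 0.14 with classes split by any Foxp3 UMI, both inside its random range of -0.11 to 0.19. Glycolysis and hypoxia genes had a median of 0.28 (0.19 to 0.35), cell cycle genes 0.39 (0.08 to 0.60) and class I antigen presentation genes 0.16 (0.10 to 0.23). The glycolysis median fell inside its random range (-0.12 to 0.16) in thinned cells (0.12), with equal weight per cell (0.159) and with classes split by any Foxp3 UMI (0.13), and the class I median was 0.02 with that split. The cell cycle median was inside its random range (-0.23 to 0.33) under 8 alternatives, such as 0.11 in thinned cells.

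Lower in the female library were naive and central memory genes, with a median of -0.34 (-0.47 to -0.18), 4 of 16 lower by at least 1.5-fold and 0 higher. They included Il7r, the interleukin 7 receptor (-0.71, -0.89 to -0.52), Tcf7, a factor of naive and memory cells (-0.57, -0.77 to -0.36) and Il6ra (-0.76, -1.24 to -0.28). The Th17 list had a median of -0.91 (-1.30 to -0.30) over 7 measured genes, of which 4 were lower and 1 higher by 1.5-fold. Tmem176a (-2.07, -3.22 to -1.02), Tmem176b (-1.09, -1.81 to -0.37) and Ahr (-0.91, -1.50 to -0.33) were lower. Rora (0.50, 0.30 to 0.71) was higher by less than 1.5-fold, so it is not the 1 higher gene counted. Il17a (-2.84) had 93% of its male UMIs in 1 cell, and with only genes of at least 50 CPM the Th17 median was -0.21. Dissociation stress genes had a median of -0.20 (-0.32 to -0.16), with 5 of 21 lower and 1 higher by 1.5-fold, such as the heat shock genes Hspa1a (-1.05, -1.31 to -0.79) and Hspa1b (-0.94, -1.19 to -0.69). The inhibitory receptor list had a median of -0.30 (-0.44 to 0.01), with 3 of 13 lower and 1 higher by 1.5-fold, and the Treg list -0.16 (-0.38 to -0.01), with 5 of 17 lower and 2 higher. Among their genes Pdcd1 was -0.52 (-0.77 to -0.28), Lag3 -1.23 (-1.92 to -0.56) and Capg -0.78 (-1.07 to -0.50), while Entpd1 was 1.22 (0.28 to 2.27; -0.20 with classes split by any Foxp3 UMI). The CD4 help list had a median of 0.02 (-0.15 to 0.17), with 3 of 13 genes higher and 1 lower by 1.5-fold. Tnf was 0.77 (0.23 to 1.35) and Tnfsf11 -0.37 (-0.69 to -0.05; 0.05 without the cells described next).

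**Figure D3:**
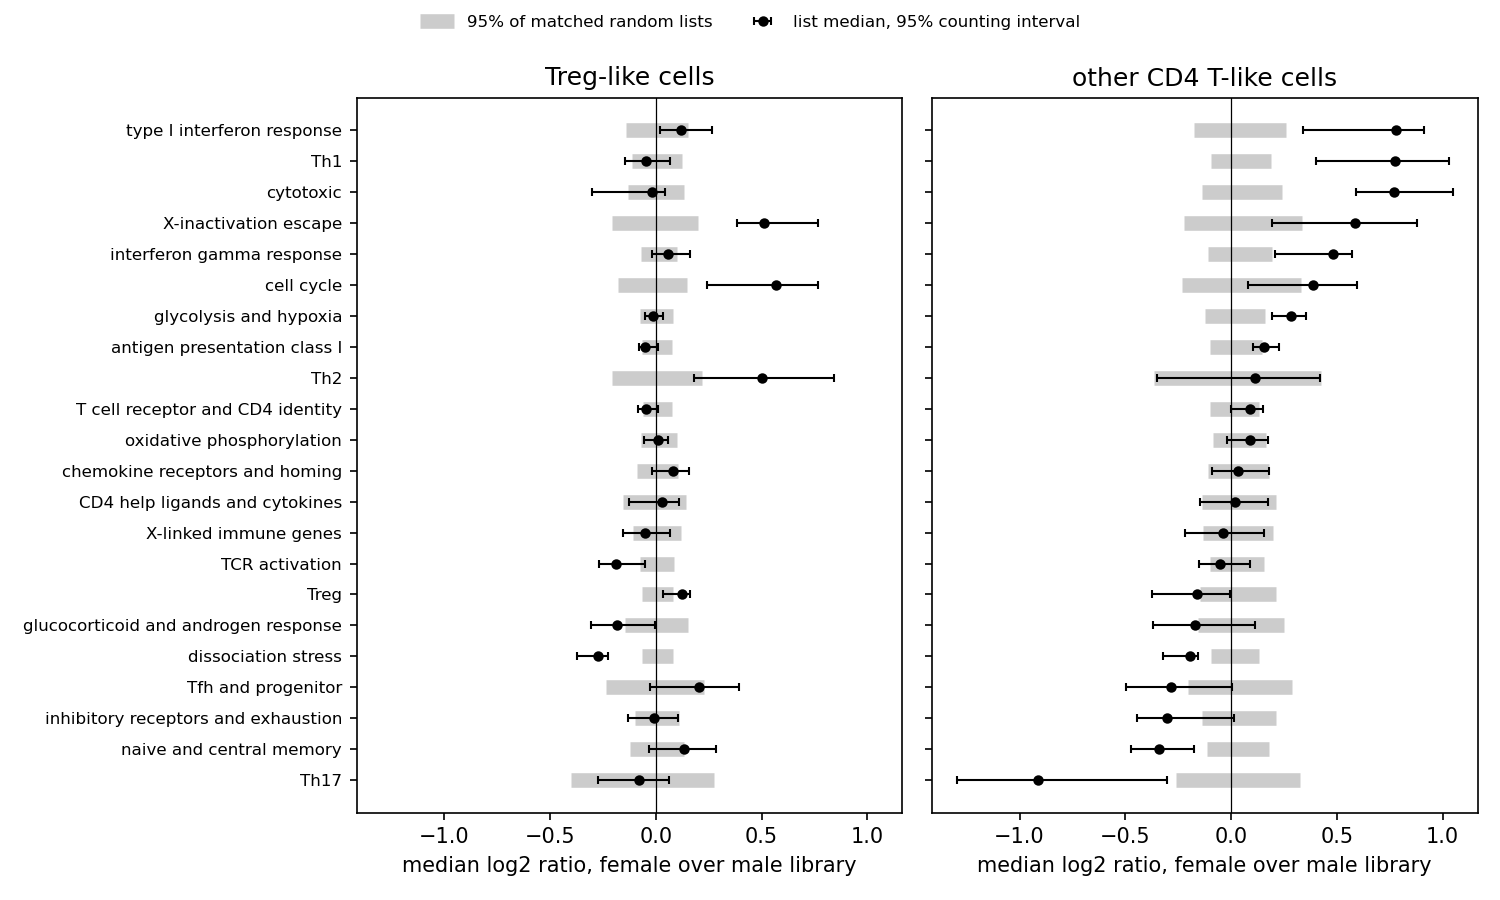
Median log2 ratio, female over male library, of each gene list in Treg-like cells (left) and other CD4 T-like cells (right); points with 95% counting intervals, grey bars holding 95% of matched random lists. In other CD4 T-like cells the Th1 median of 0.77 lies above its grey bar and the Th17 median of -0.91 below it.

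The highest ratios in other CD4 T-like cells were those of Klrg1, an inhibitory receptor of differentiated T cells (151 and 3 UMIs, log2 4.93, 3.36 to 7.23), Csf1, a macrophage growth factor (62 and 2 UMIs, 4.23, 2.32 to 7.31), Rbm47 (64 and 3 UMIs, 3.69, 2.08 to 6.01) and Grb7 (30 and 2 UMIs, 3.19, 1.21 to 6.30). At Leiden resolution 2, a finer cluster led by Klrg1, Il12rb2, Il18rap and Ifng held 70 of the 268 female cells (26.1%, 21.0% to 31.8%) and 3 of the 183 male cells (1.64%, 0.339% to 4.72%). Without it the Th1 median was 0.17 (0.06 to 0.38), the naive median -0.05, the cytotoxic median 0.43, the glycolysis median 0.07 and the class I median 0.02, and since Th1 genes lead this cluster, leaving it out lowers the Th1 median by construction. A cluster this unequal may not be separable from the library it came from. The lowest ratios were those of the neutrophil genes S100a9 and S100a8, at least 62.6-fold and 58.2-fold lower with 0 set to 3 counts (50.1-fold and 46.5-fold at the interval bounds), with all 114 and 106 UMIs in 1 male cell, followed by Il17a, given above, and Eif4ebp1 (-2.46, -4.06 to -1.09). Klrg1 (ENSMUSG00000030114) lies on chromosome 6 at 122270596 to 122282882 and Il12rb2 (ENSMUSG00000018341) on chromosome 6 at 67291318 to 67376188. Ifng (ENSMUSG00000055170) lies on chromosome 10 at 118441046 to 118445892 and Il18rap (ENSMUSG00000026068) on chromosome 1 at 40515362 to 40551705.

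**Figure D4:**
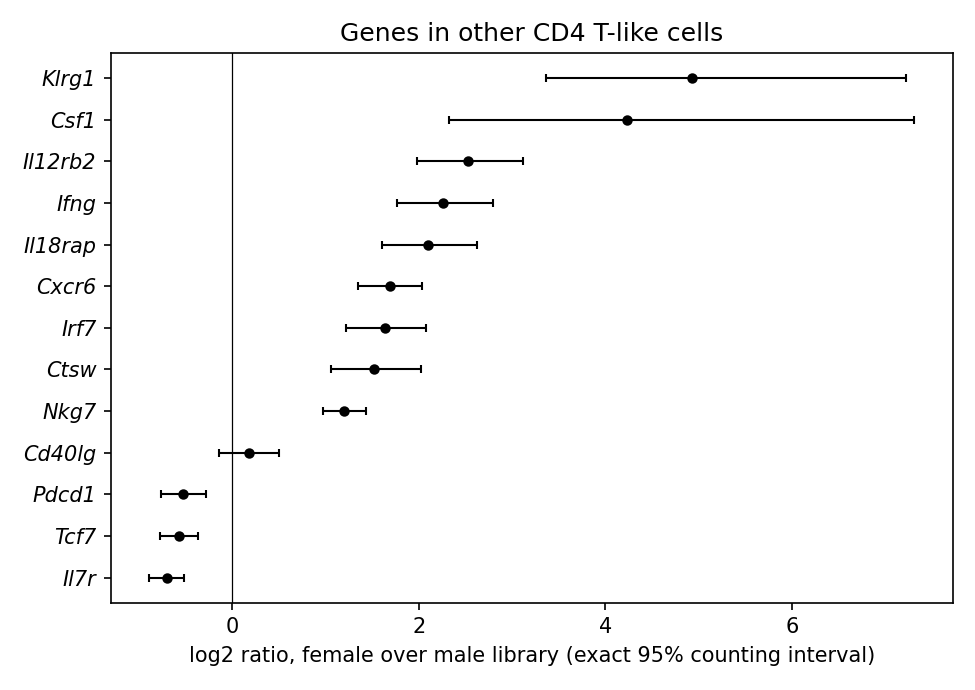
Log2 ratio, female over male library, of 13 genes in other CD4 T-like cells with exact 95% counting intervals; the genes were picked for display after their values were seen. Klrg1 at 4.93 and Csf1 at 4.23 rest on 3 and 2 male UMIs.

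In Treg-like cells of the female library Il1rl1 and cell cycle genes were higher, and activation and stress genes were lower, as they were in part of the Cd8-high clusters. The dissociation stress list had a median of -0.27 (-0.37 to -0.23), with 9 of 21 genes lower and 0 higher by 1.5-fold, below all of the random lists. The immediate early genes Jun (-1.10, -1.28 to -0.93) and Fos (-1.0, -1.14 to -0.86) were among them. The T cell receptor activation list had a median of -0.19 (-0.27 to -0.05), with 4 of 18 lower and 0 higher, including Nr4a1 (-0.71, -0.83 to -0.60), Egr1 (-0.76, -1.06 to -0.47) and the phosphatase gene Dusp2 (-0.81, -1.02 to -0.61). Lower stress genes were not limited to Treg-like cells. Beside other CD4 T-like cells, given above, the stress median was -0.16 (-0.29 to -0.11) in Cd8-high cluster 7, -0.10 in clusters 0 and 2 and -0.02 in clusters 4 and 12. The activation median was -0.10 in clusters 7 and 0, -0.08 in cluster 2, 0.16 in cluster 4 and 0.07 in cluster 12. Klf2, a factor for exit from tissue, was -1.12 (-1.27 to -0.98). Il10, a suppressive cytokine, was -0.65 (-0.91 to -0.40), and Areg, a growth factor for tissue repair, -0.57 (-0.67 to -0.47). The chemokine Ccl3 was -0.99 (-1.31 to -0.67).

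Higher in these cells were Il1rl1, the interleukin 33 receptor (1.02, 0.66 to 1.37), the chemokine receptor Ccr3 (1.11, 0.62 to 1.60) and Ikzf4 (0.62, 0.34 to 0.90). The Th2 list, which holds Il1rl1 and Ccr3, had a median of 0.50 (0.18 to 0.84) over 5 genes, 2 higher and 0 lower by 1.5-fold. The Treg list had a median of 0.13 (0.04 to 0.16), inside its random range (-0.06 to 0.08) under 5 alternatives, such as 0.06 in thinned cells. Cell cycle genes had a median of 0.57 (0.24 to 0.77), with 8 of 17 higher and 0 lower, such as Ube2c (1.42, 0.97 to 1.88) and Mki67 (0.92, 0.41 to 1.45). Cluster 9, led by histone genes, Mki67 and Top2a, held 426 female and 308 male barcodes of the mixed class, so the cycling cells in it are outside this comparison. With cluster 11 counted as Treg-like the cell cycle median was -0.07 and the Treg median -0.05. The largest differences by the naming rule were lower Def8 (-2.33, -3.15 to -1.59) and Akap6 (-1.74, -2.78 to -0.83), and higher Lrig1 (1.60, 0.95 to 2.28), Rflnb (1.42, 0.71 to 2.15) and Aacs (1.36, 0.71 to 2.03). Ly6c2 (-1.78, -2.32 to -1.27) and Ifitm1 (-2.79, -4.05 to -1.75) were lower, but without cells holding a Cd8a or Cd8b1 UMI they were 1.36 and 1.01. Ifitm1 had 72.5% of its male UMIs in 1 cell. H2-Aa (-1.92) and Gzma (-1.67) likewise had 75% and 76.2% of their male UMIs in 1 cell, and Xcl1 (1.78) had 86% of its female UMIs in 1 cell. Gzma was 1.22 without cells holding a Cd8a or Cd8b1 UMI, and Xcl1 was -0.28 with cluster 11 added. Il1rl1 (ENSMUSG00000026069) lies on chromosome 1 at 40429570 to 40465415 and Def8 (ENSMUSG00000001482) on chromosome 8 at 123423527 to 123463270.

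Over the pooled CD4 T-like cells, the female library had less of the Treg and inhibitory receptor lists and more of the Th1 list, with the class shares differing as given above. The Treg list had a median of -0.28 (-0.31 to -0.20), with Foxp3 at -0.53 (-0.63 to -0.42), and the inhibitory receptor list -0.23 (-0.31 to -0.14), with Lag3 at -0.73 (-0.84 to -0.63). With cluster 11 added the Treg median was -0.12 and the inhibitory median -0.04, inside its random range (-0.11 to 0.11), and over all kept cells the inhibitory median was 0.03. The Treg median was -0.10 without the Klrg1-led cells. The Th1 list had a median of 0.38 (0.23 to 0.48). It was 0.05 without the Klrg1-led cells and 0.04 with cluster 11 added. The CD4 help list had a median of 0.14 (0.04 to 0.38), with 4 of 13 genes higher and 0 lower by 1.5-fold, and was -0.11 with cluster 11 added, 1 of 8 alternatives that put it inside its random range (-0.14 to 0.12). The rule for pooled cells took genes whose ratios had the same sign in both classes, whatever their size there. By this rule the lowest pooled ratios included those of Def8 (-2.60, -3.38 to -1.90), the receptor Gpr55 (-1.33, -1.66 to -1.0), Ccdc184 (-1.23, -1.63 to -0.84), the phosphatase gene Dusp16 (-1.21, -1.62 to -0.81), Laptm4b (-1.20, -1.55 to -0.85) and the linker histone gene H1f0 (-1.09, -1.35 to -0.83). Upp1, Ccl3, Cxcl2, Gas2, Kansl1l and Myo10 were also lower, from -1.59 to -1.10, and Myo10 was 0.04 with cluster 11 added. All 12 had counting intervals below 0 in Treg-like cells. Gpr55 (-1.55, -2.91 to -0.29) and H1f0 (-0.72, -1.35 to -0.09) did so in other CD4 T-like cells, where the intervals of Dusp16 and Kansl1l held 0, and the remaining 8 had too few UMIs to be measured. The highest pooled ratios by the rule were those of Il18rap (1.68, 1.36 to 2.0), the ganglioside enzyme gene St8sia1 (1.55, 1.0 to 2.14), Spsb1 (1.53, 0.88 to 2.23), Ctsw (1.39, 1.08 to 1.70), Il12rb2 (1.36, 1.10 to 1.63) and Anxa1 (1.35, 0.73 to 1.99). Slamf7, Lax1, Plac8, N4bp3, Rbm47 and Parp8 followed, from 1.23 to 0.94, and Slamf7 was -0.03 with cluster 11 added. Ifng was higher still in pooled cells, with 309 female and 66 male UMIs (2.35, 1.96 to 2.75), but fell outside the rule because its ratio in Treg-like cells was -0.24, and it was -0.10 with cluster 11 added. Counting intervals lay above 0 in both classes for Spsb1 and Ctsw only. In Treg-like cells the intervals of Il18rap, Il12rb2, Lax1, Plac8, N4bp3 and Rbm47 held 0, as in Il12rb2 (0.22, -0.15 to 0.60), and St8sia1, Slamf7 and Parp8 were not measured. Those of Anxa1 and Parp8 held 0 in other CD4 T-like cells.

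As a list, genes that escape X inactivation were higher in the female library in both CD4 T-like classes. Medians were 0.51 (0.38 to 0.77) in Treg-like and 0.59 (0.19 to 0.88) in other CD4 T-like cells. All 8 measured genes were higher in Treg-like cells. In other CD4 T-like cells 5 of 7 were higher and 2 lower, 1 of the lower by at least 1.5-fold. The histone demethylase gene Kdm6a was 0.75 (0.36 to 1.14) and 1.02 (0.44 to 1.62), and Mid1 0.78 (0.52 to 1.04) and 0.76 (0.35 to 1.19). In other CD4 T-like cells thinned to 2977 UMIs the list median was 0.10, inside its random range of -0.22 to 0.33. X-linked immune genes as a list had medians of -0.05 and -0.04. Nr3c1, the glucocorticoid receptor, was 0.33 (0.15 to 0.50) in Treg-like and 0.09 (-0.13 to 0.31) in other cells. The steroid receptor list, to which Nr3c1 belongs, had too few measured members for a comparison with random lists. Glucocorticoid and androgen response genes had medians of -0.18 (-0.31 to -0.01) in Treg-like and -0.17 (-0.37 to 0.12) in other cells. The remaining lists had medians with intervals holding 0 in Treg-like and other CD4 T-like cells, respectively: T follicular helper and progenitor genes 0.21 and -0.28, chemokine receptors 0.08 and 0.03, oxidative phosphorylation 0.01 and 0.09, and T cell receptor and CD4 identity -0.05 and 0.09.

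The Cd8-high cells were compared by cluster number, a comparison added after the data were seen. Cluster 7, led by Prf1, Pdcd1 and Havcr2, genes of killing and exhaustion, held 19.6% of female and 10.8% of male cells. Cluster 4, led by Klf2, Tcf7 and Lef1, genes of naive cells, held 5.28% and 10.9%. In all 5 of the largest Cd8-high clusters Cdk5rap1 (median log2 1.52), the peptide transporter gene Slc15a2 (1.45), the zinc exporter gene Slc30a1 (1.24), Mid1 (1.21), the metallothionein gene Mt1 (1.17) and Metrnl (0.81) were higher in the female library. Klf2 (median -0.67), Rhob (-0.74), Hspa1b (-0.78) and Ankrd46 (-0.82) were lower in all 5. The same direction in all 5 was the rule by which these genes were taken, so it is not a result. Sizes differed by cluster, as in Mt1 (0.27 in cluster 7, 1.60 in cluster 2). Hspa1b was -0.22 in cluster 12 and -1.34 in cluster 0, and Ankrd46 -0.09 in cluster 7 and -1.11 in cluster 2.

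The start of the T cell receptor transcript shows which variable segment a cell uses, which is not the same as its clone. In cluster 7 Trbv20 was the most counted segment in 143 of 658 female cells (21.7%, 18.6% to 25.1%) and 11 of 371 male cells (2.96%, 1.49% to 5.24%). Trbv5 led in 4.41% (2.97% to 6.27%) and 18.3% (14.5% to 22.6%). Trbv12-2 led in other CD4 T-like cells in 57 of 241 female cells (23.7%, 18.4% to 29.5%) and 12 of 147 male cells (8.16%, 4.29% to 13.8%). In Treg-like cells Trbv12-2 led in 17.4% (12.4% to 23.4%) and 8.72% (5.78% to 12.5%), and in cluster 7 the direction was opposite, with 12.5% (10.0% to 15.2%) and 25.6% (21.2% to 30.4%). Trbv15 led in Treg-like cells in 1.99% (0.545% to 5.02%) and 10.4% (7.18% to 14.4%).

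Markers of other cell types differed between the libraries. Over all kept cells the dendritic cell list stood at 263 CPM in the female and 520 CPM in the male library (log2 -0.99, -1.01 to -0.96), the neutrophil list at 23.8 and 62.8 CPM (-1.40) and the fibroblast list at 55.6 and 98.6 CPM (-0.83). The B cell list was at 34.6 and 51.4 CPM, the mast cell and basophil list at 3.58 and 4.75 CPM, the endothelial list at 23.6 and 27.6 CPM and the erythroid list at 0.288 and 0.454 CPM. The epithelial or tumour list was at 205 and 146 CPM (0.49), the gamma-delta T cell list at 25.2 and 21.9 CPM, and the macrophage and monocyte list at 1131 and 1047 CPM. The natural killer cell list was at 181 and 182 CPM, the list of group 2 innate lymphoid cells at 763 and 725 CPM and the CD8 pair at 1308 and 1230 CPM. The most counted gene was Ly6c2 in the macrophage list and Cxcr6 in the innate lymphoid list. Ly6c2 is also a leading gene of Cd8-high cluster 0 and Cxcr6 of cluster 7, so these lists do not measure those cell types alone. Mixed cluster 10, with Lyz2 and Il1b among its leading genes, held 1.61% of female and 3.04% of male cells. In Treg-like cells the dendritic cell list was lower in the female library (-0.49, -0.60 to -0.38) beside the lower stress genes. The gamma-delta T cell list there had 0 female and 21 male UMIs (-2.28 with 0 set to 3 counts, upper bound -1.85). In other CD4 T-like cells the macrophage and monocyte list was 1.09 (0.80 to 1.39), through Ly6c2, which the Th1 list also holds (1.37), the list of group 2 innate lymphoid cells 0.81 (0.67 to 0.95), which holds Klrg1 and Cxcr6, the B cell list -0.70 (-1.24 to -0.15) and the CD8 pair 0.34 (-0.12 to 0.82). Beside the lower Th17 genes there, the gamma-delta T cell list was also lower (-1.17, -1.86 to -0.49), as was the neutrophil list (-4.25), through the male cell with S100a9.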

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

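Among the tests below, those on the mixed clusters and on Cd40lg were chosen after the result they measure was seen, and the 3 on the Th1 genes before. The differences between Treg-like and other CD4 T-like cells listed next were not tested.

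Genes of the fixed lists with opposite directions in the Treg-like and other CD4 T-like cells were taken up where both counting intervals excluded 0, each class held at least 50 UMIs and no cell held over 50% of them, a filter set after the data were seen. In Treg-like and other CD4 T-like cells, in that order, the log2 ratios of female over male were -1.78 and 1.37 for Ly6c2, -0.39 and 4.23 for Csf1, and -0.22 and 1.69 for Cxcr6. They were -0.85 and 0.67 for Klrd1, -0.37 and 1.04 for Klrc1, and -0.81 and 0.23 for Dusp2. For the metabolic and stress genes Slc2a3 and Ddit4 they were -0.55 and 0.86, and -0.14 and 0.79. Capg alone was higher in Treg-like and lower in other cells, at 0.13 and -0.78. The opposite directions of 5 of these genes did not hold under every alternative, for a cause that was not tested. The rest are not shown to hold, since alternatives were run only for genes that the naming rule took in that class. In Treg-like cells Ly6c2 was 1.36 without cells holding a Cd8a or Cd8b1 UMI, 0.13 without barcodes with 2 or more Trbv segments and 0.25 with cluster 11 added. Klrd1 there was 0.33 under the stricter cell filter, 0.70 without barcodes with 2 or more Trbv segments and 0.14 with cluster 11 added, where Slc2a3 was 0.000975. In other CD4 T-like cells Klrc1 was -0.60 and Ddit4 -0.15 at Leiden resolution 2, Ddit4 was -0.60 with classes split by any Foxp3 UMI, and Slc2a3 was -0.20 without the Klrg1-led cluster.

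Outside the T cell comparisons lay the tumour-like cells, in which Krt8 stood at 1932 CPM in the 41 female and 2016 CPM in the 30 male cells. This class was set by Krt8 above 500 CPM, so a high level follows from the choice of the cells.

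Mixed clusters held Foxp3 with Cd8a or Cd8b1 UMIs in the same barcodes. Free RNA from Treg-like cells is argued against by 2.73 Foxp3 UMIs per barcode there against 0.155 in tumour-like cells, a class set without regard to Foxp3, a 17.6-fold difference (9.82 to 35.3), although the mixed clusters were picked partly by Foxp3, through at least 25% of barcodes with a Foxp3 UMI and Cd8a or Cd8b1 UMIs, which asks for far less than this level. At 10000 UMIs per barcode, 26.6% of barcodes in mixed and 7.66% in Cd8-high clusters had at least 3 Trbv segments, 18.9 percentage points more, which is consistent with more than 1 cell per barcode. Single cells that express both genes stay open as part of the mixture, since 33.4% of the 467 co-detecting barcodes had at least 3 segments and a barcode with a pair of cells need not show them. The sex of the mice was not tested as an explanation, and the mixed share was 21.5% and 21.0% in the libraries of the 2 sexes.

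Pooled Cd40lg was higher in CD4 T-like cells of the female library. In thinned cells the log2 ratio was 0.83, which cannot decide on a depth gap. The ratio is already scaled to UMI totals, and thinning kept the classes and each cell's expected share of each gene. A lower Treg-like share may account for the difference, since at equal class weights the ratio was 0.0722, and that share could itself come from the sort, the digestion or the sex of the mice. A higher level within other CD4 T-like cells cannot be told apart from none at this depth, with a log2 ratio of 0.18 and an interval from -0.14 to 0.50.

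Th1 genes were higher in other CD4 T-like cells of the female library. Cd8-high cells in the cluster are argued against as the whole cause by a median of 0.65 without cells holding a Cd8a or Cd8b1 UMI. Cells with Trbv12-2 are argued against as the whole cause by 0.72 without them. In thinned cells the median was 0.64, which cannot decide on a depth gap, for the reason given for Cd40lg. Each lower counting bound, 0.41, 0.37 and 0.37, stayed above the range of 95% of random lists. Without barcodes with 2 or more Trbv segments the Th1 median was 0.36. At 10000 UMIs, 5 of 28 barcodes of this class had at least 3 segments (17.9%, 6.06% to 36.9%). The share was 10.5% in the female and 33.3% in the male library, but these 28 barcodes are too few to compare the libraries. More than 1 cell per barcode was not tested as a cause of the Th1 difference. Without the Klrg1-led finer cluster of 70 female and 3 male cells the median was 0.17, but Th1 genes lead that cluster, so this restates the difference and explains none of it. The sex of the mice, single mice and sample handling stay open and were not tested.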

How the results depend on the processing

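Among the alternatives below, those that add cluster 11 to the Treg-like class or leave out barcodes, cells, the Klrg1-led cluster or genes that hold ribosomal RNA reads, and the single thinning draw, were chosen after the data were seen. No paired analysis was possible because there was 1 library per sex. Over 349 results and 23 alternatives, 5511 of 5981 values stayed within the counting interval of the reported value, 413 left it without a change of sign from a called value, and 57 changed sign from a called value. The difference in Treg-like share was negative under every alternative that gave a value, from -20.0 to -13.6 percentage points. Cd40lg in pooled cells ranged from -0.04 to 0.83 and in other CD4 T-like cells from 0.05 to 0.33. The difference in the thinned Cd40lg share was 3.45 percentage points in the first single draw, and 95% of 1000 draws lay between -0.136 and 9.86. Keeping doublets changed nothing because none were called, and no CD4 T-like cluster was cycling, so these 2 alternatives test nothing. Keeping doublets is nevertheless 1 of the 23 alternatives counted, so its values, the same by construction, add to the 5511. Leiden resolution 0.5 gave values for Treg-like cells only, since no cluster of other CD4 T-like cells formed. Values below are log2 ratios, with medians for lists. Values that left the interval are listed for the planned results, and for gene lists picked after the data were seen because median and interval lay outside 0 and the random range, and the cause of each shift was not tested. With TMM factors, the sign changed in pooled cells for class I presentation 0.00858. With equal weight per cell, the sign changed in pooled cells for CD4 help -0.0362. Outside the interval were values in pooled cells for inhibitory receptors -0.33, Treg -0.35 and cytotoxic 0.56, and in other CD4 cells for stress -0.14 and glycolysis 0.16. With thinned cells, the sign changed in pooled cells for type I interferon -0.0584, and in Treg-like cells for type I interferon -0.0295 and Isg15 -0.13, and in other CD4 cells for Per1 0.0254. Values left the interval in pooled cells for inhibitory receptors -0.35, Treg -0.37, Th1 0.49 and cytotoxic 0.54, and in Treg-like cells for stress -0.40, and in other CD4 cells for glycolysis 0.12 and X escape 0.0958. With no list minimum beyond 1 UMI in each library, values left the interval in pooled cells for cytotoxic 0.00468, Tfh 0.33, cell cycle 0.63 and TCR activation -0.22, and in Treg-like cells for cell cycle 0.78. With list members of at least 50 CPM, values left the interval in pooled cells for CD4 help 0.0307, cell cycle 0.0325 and stress -0.0919, and in other CD4 cells for Th17 -0.21. Under the stricter cell filter, the sign changed in Treg-like cells for Gzma 0.41 and Klrd1 0.33. Values left the interval in pooled cells for CD4 help 0.0158 and cytotoxic 0.76, and in other CD4 cells for type I interferon 0.0371, interferon gamma 0.18 and glycolysis 0.36. With all barcodes, the sign changed in Treg-like cells for Gzma 0.35. Outside the interval were values in pooled cells for Th1 0.17, cell cycle 0.0768 and stress -0.31, and in Treg-like cells for cell cycle 0.22, and in other CD4 cells for cytotoxic 0.46 and stress -0.37. At Leiden resolution 2, the sign changed in pooled cells for CD4 help -0.0988 and cytotoxic -0.0558, and in other CD4 cells for Ccl4 -3.71, Klrc1 -0.60 and Ddit4 -0.15. Values left the interval in other CD4 cells for cytotoxic 0.20, naive -0.17, stress -0.15 and glycolysis 0.18. With classes split by any Foxp3 UMI, the sign changed in other CD4 cells for Ccl4 -3.04, Entpd1 -0.20 and Ddit4 -0.60. Outside the interval were values in Treg-like cells for stress -0.22, and in other CD4 cells for Treg -0.61, Th1 0.37, interferon gamma 0.14, stress -0.40, glycolysis 0.13 and class I presentation 0.0200. Over all kept cells, the sign changed in pooled cells for Cd40lg -0.0376, CD4 help -0.18, inhibitory receptors 0.0292, Tfh -0.37, chemokine receptors -0.0779, glycolysis 0.0308 and class I presentation 0.00124. Values left the interval in pooled cells for Treg -0.17, Th1 0.00326, Th17 -0.0359 and TCR activation -0.20. With cluster 11 added to Treg-like, the sign changed in pooled cells for CD4 help -0.11, cytotoxic -0.0391, cell cycle -0.0624, class I presentation 0.00740, Myo10 0.0358, Slamf7 -0.0305, Ifng -0.10, Xcl1 -0.38, Ube2c -0.0312, Stmn1 -0.0571 and Irf8 0.36, and in Treg-like cells for Treg -0.0529, cell cycle -0.0688, Ifitm1 0.27, Ly6c2 0.25, Xcl1 -0.28, Pdcd1 0.18, Tox -0.0961, Gzma 0.24, Klrd1 0.14, Iigp1 -0.00793, Slc2a3 0.000975 and Egln3 -0.12. Outside the interval were values in pooled cells for inhibitory receptors -0.0396, Treg -0.12, Th1 0.0416, Tfh 0.0366 and Th2 0.77, and in Treg-like cells for Th2 0.85 and stress -0.19. Without barcodes with 2 or more Trbv segments, the sign changed in Treg-like cells for Ly6c2 0.13, Gzma 1.51 and Klrd1 0.70. Values left the interval in pooled cells for cytotoxic 0.58, Th17 -0.17 and Th2 0.60, and in other CD4 cells for Th1 0.36, cytotoxic 0.52 and class I presentation 0.0465. Without cells holding a Cd8a or Cd8b1 UMI, the sign changed in Treg-like cells for Ifitm1 1.01, Ly6c2 1.36 and Gzma 1.22. Outside the interval were values in pooled cells for inhibitory receptors -0.33 and cytotoxic 0.78. Without the Klrg1-led cluster, the sign changed in pooled cells for cytotoxic -0.12, and in other CD4 cells for Tnfsf11 0.0485 and Slc2a3 -0.20. Values left the interval in pooled cells for Treg -0.0983 and Th1 0.0464, and in other CD4 cells for Th1 0.17, cytotoxic 0.43, naive -0.0548, stress -0.0994, glycolysis 0.0655 and class I presentation 0.0204. Without cells with Trbv12-2, values left the interval in other CD4 cells for naive -0.16 and stress -0.16. Without the top cell per gene, the sign changed in pooled cells for Il17a 0.33.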

Other observations

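No test was run for the values below, which were chosen after the data were seen.

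The 71 tumour-like cells expressed the keratins Krt8 and Krt18 (1915 CPM in the female and 1912 CPM in the male library) and the surface gene Tm4sf1 (542 and 555 CPM). Xist had 23 UMIs in the female library's tumour-like cells. Ddx3y and Eif2s3y had 2 UMIs each in those of the male library, and Kdm5d and Uty had 0, which allows up to 2.31 CPM at 3 counts. Cd3e had 142 and 44 UMIs in these cells.

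Of the female cells in the Klrg1-led finer cluster that had a Trbv segment, 26 of 68 had Trbv12-2 as the most counted one. Cluster 11, the mixed cluster led by Foxp3 with Penk, Areg and Il5, had 36.0% (31.8% to 40.4%) of its barcodes with at least 3 Trbv segments at 10000 UMIs, against 3.45% (0.947% to 8.59%) of Treg-like cells.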
